A study of Mus musculus with 2 samples.

How the data were processed

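Per the labels, the series holds long-read RNA sequencing of adrenal gland from female B6CASTF1/J mice aged 18 to 20 months, as 1 group of 2 libraries from 1 µg of total RNA each. The study question was not given in the sources used here. For each library the authors deposited a table of transcript models with their counts and a transcript annotation. Per the file headers and the text deposited beside them, the counts are numbers of long reads assigned to each model on mm10 with GENCODE M21, and the field names are those of the TALON program. The deposited counts carry no normalization, only models with at least 1 read are listed, and the aligner, program version and read filters are not stated. Models new to the annotation are numbered per library, and 0 new model identifiers were shared.

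Replicate 1 held 1478362 reads on 130376 models and replicate 2 held 1007541 reads on 118745 models. Of the models, 60.1% and 61.4% had 1 read. ERCC spike-in RNAs, with 18340 and 15552 reads on 49 and 48 sequences, were left out of gene totals and tests. The tables hold no SIRV sequences, which per the labels were added too. Counts were summed per annotated gene over all its models, 1412947 and 933963 reads. Reads on gene models new to the annotation, 3.22% and 5.85% of mouse reads, were left out of gene tests because their identifiers do not match between libraries. CPM values use these gene totals. Ratios are replicate 2 over replicate 1 after TMM scaling (factors 0.989 and 1.01), with a prior of 0.5 counts for log2 ratios. Ratios of single spike-in sequences use each library's spike-in total instead, without a prior. At a count of 0 the fold is given as a bound against 3 reads, without counting error in the other library.

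The design, tests, gene lists and alternatives were fixed before the data were examined. Genes with at least 10 reads over both libraries, 11068 of 17707, were compared by an exact binomial test conditional on the gene's total, with Benjamini-Hochberg adjustment at 0.05. As the group has no second condition, this compares libraries, and its p-values cover counting error alone. The common dispersion was estimated in edgeR with an intercept-only design and used in edgeR's exact test, so the spread comes from the same libraries that are compared. For each of 23 gene lists the share of reads with its exact interval and the median log2 ratio of measured members were taken. Medians were set against 10000 random lists drawn from 20 expression bins, for lists of at least 3 measured members. Lists for skeletal muscle, thermogenic fat, general adipocytes, the Akr1c family and nuclear noncoding RNA, were added after gene ratios had been seen.

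Isoforms were matched between libraries by identifier when annotated and by chromosome, strand and intron chain when not. Unannotated single-exon models of a gene were treated as 1 isoform, and this key was chosen after the files were seen. Genes with at least 20 reads in each library were measured, and the share of the most abundant isoform was compared by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment. New spliced isoforms are NIC and NNC models with at least 5 reads in a library, counted as shared when the other library holds the same intron chain.

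Genes were named by a rule fixed before the data were examined. It took the 25 nuclear genes with the highest mean CPM and up to 4 members of each list with the highest mean CPM, or members with 0 reads. It also took the 12 genes with the largest and the 12 with the smallest ratio among those with 100 or more reads. From the isoforms it took a panel of 32 genes, the 10 largest differences in main isoform share past the test, and the 10 most abundant new isoforms in both libraries. Other genes, among them Foxl2, H2-Aa, H2-Eb1, Plin1, Fabp4, Gm45233, Podn and Rtl8c, were chosen after their values were seen. Of the panel, Snap25, Slc18a1, Ddc, Fn1, Hsd11b2 and Sult1e1 had too few reads to be measured.

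Alternatives covered DESeq2 size factors, total counts and spike-in totals, other read minimums, known transcripts only, thinning to equal depth, a chi-square test over all isoforms, leaving out incomplete splice matches and genomic models, matching of both ends within 100 bp, and leaving out each library. Added after seeing the data were spike-in scaling of the list counts and of the coefficient of variation, exact coordinates for single-exon models, random lists matched on length in 10 bins and expression in 5 bins, and pooling of models on the same strand whose exons overlap. Transcript lengths were those of each gene's most abundant annotated transcript, known for 93.6% of genes in the length tests. The Gm15459 sequence was compared with Hspa8 using minimap2 2.31. Other tools were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Random draws used the seed 20211.

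The steps were tested on simulated data of the same depth with set changes. The binomial test, on counts with counting error alone, recovered 86% of 2-fold and 99% of 4-fold changes with 4 false calls among 189. edgeR's exact test, on counts with a coefficient of variation of 20%, recovered 1% of 2-fold and 36% of 4-fold changes with 0 false calls among 37, and found a coefficient of 23.6%. Of 20 unshifted lists matched on expression 5% fell outside the random range, and of lists shifted by 0.5 all did. These lists held 20 randomly drawn genes each, on counts with counting error alone. The result therefore does not cover smaller lists, spread beyond counting error or genes that vary together. The Fisher test recovered 92% of share changes of 30 points with 10 false calls. All 200 genes set under 50% were found, as were all 60 shared new isoforms.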

Results

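Long-read RNA sequencing, which reads transcripts as single long molecules, was applied to adrenal gland RNA from aged female mice of the F1 hybrid strain B6CASTF1/J. The adrenal gland makes steroid hormones in its cortex and catecholamines in its medulla. The series holds 1 group of 2 libraries, which the labels number as biological replicates 1 and 2. Each was made from 1 µg of total RNA from mice aged 18 to 20 months. The labels give each library its own biosample but the same donor entry, so the sources used here do not settle whether the libraries come from separate animals. Replicate 1 held 1478362 reads and replicate 2 held 1007541 reads on transcript models. Of these, 1412947 and 933963 reads fell on annotated mouse genes. ERCC spike-in RNAs took 1.24% and 1.54% of the reads. With no other condition in the series, the comparisons concern what the gland expressed, in which isoforms, and how far the libraries differed. Intervals are exact 95% Clopper-Pearson intervals unless stated, and they cover counting error only. A count of 0 allows up to 3 reads, or 2.12 CPM (counts scaled to equal library totals) in replicate 1 and 3.21 CPM in replicate 2.

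The most abundant nuclear genes were those of steroid synthesis. Cyp11a1, which encodes the side-chain cleavage enzyme that opens the pathway from cholesterol, stood at 18880 ± 538 CPM (mean ± SD, n = 2). Cyp11b1, whose product makes corticosterone, reached 16966 ± 4854 CPM, and the 21-hydroxylase gene Cyp21a1 reached 16768 ± 1655 CPM. Star, which carries cholesterol into mitochondria, stood at 10446 ± 2961 CPM and Hsd3b1 at 8629 ± 168 CPM. The 20 genes of the steroidogenesis list together took 8.22% of gene reads in replicate 1 (interval 8.18 to 8.27%) and 8.14% in replicate 2 (interval 8.09 to 8.20%), a mean of 8.18 ± 0.0576%. Of the 20, 19 were detected in both libraries, and Hsd11b2 had 1 and 0 reads. Other members included Akr1b7, at 2416 ± 602 CPM, the electron donors Fdxr, at 1674 ± 418 CPM, and Fdx1, at 1413 ± 932 CPM, and the transcription factor gene Nr5a1, at 1318 ± 406 CPM.

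Among the other leading genes were several of lipid and steroid metabolism. Acly, which supplies acetyl-CoA, stood at 4920 ± 1939 CPM, Adh1 at 3541 ± 138 CPM, the desaturase gene Fads2 at 3526 ± 267 CPM, Akr1d1 at 2746 ± 322 CPM, and the efflux transporter gene Abcb1b at 2686 ± 1118 CPM. Of chaperone genes, Hspa8 stood at 4069 ± 481 CPM, Hsp90ab1 at 3869 ± 808 CPM and the mitochondrial Hspd1 at 3677 ± 571 CPM. The ATP synthase genes Atp5b and Atp5a1 stood at 3578 ± 537 and 3050 ± 623 CPM, and the mitochondrial protease gene Lonp1 at 3233 ± 129 CPM. The 25 most abundant nuclear genes also held Gsn, Aldoa, Malat1, Car3, Ubb, Cebpb and Ctsd, between 2527 ± 241 CPM for Ctsd and 3135 ± 72.2 CPM for Gsn. The top 5 genes held 7.21% of gene reads in replicate 1 and 7.13% in replicate 2. The 28 genes of cholesterol supply, led by the lipoprotein receptor gene Scarb1 (2199 ± 560 CPM) and by Apoe (1603 ± 749 CPM), took 0.885 ± 0.121% of gene reads. The 22 antioxidant genes took 0.731 ± 0.0145%, led by the peroxiredoxin genes Prdx1, at 1190 ± 89.9 CPM, and Prdx2, at 983 ± 168 CPM.

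Markers of each adrenal zone were read. Cyp11b2, the aldosterone synthase gene of the zona glomerulosa, stood at 1403 ± 379 CPM and the potassium channel gene Kcnk3 at 1474 ± 25.5 CPM. In the replicate 1 annotation the span of Cyp11b2 (chromosome 15, 74834919 to 74856318) overlaps that of Cyp11b1 (74825189 to 74841643) on the same strand. How far reads of Cyp11b1 were assigned to Cyp11b2 was not tested. The zona glomerulosa list took 2.03 ± 0.112% of gene reads, although Cyp21a1, which the whole cortex uses, held most of them. The zona fasciculata list took 3.40 ± 0.329%. The X-zone, a layer of the inner cortex in mice, was represented by Akr1c18, a progesterone-metabolising enzyme gene with 441 reads in replicate 1 and 2578 reads in replicate 2. Of the medulla, Chgb and Chga, which encode proteins of the chromaffin granule, were among the most abundant genes at 4579 ± 713 and 4427 ± 773 CPM. Th, the gene of the rate-limiting enzyme of catecholamine synthesis, stood at 1273 ± 355 CPM, and Pnmt, whose product makes adrenaline, at 337 ± 36.0 CPM. The 26 chromaffin genes took 1.46% of gene reads in replicate 1 (interval 1.44 to 1.48%) and 1.16% in replicate 2 (interval 1.14 to 1.18%), a mean of 1.31 ± 0.212%.

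Other cell types of the gland and its surroundings were seen at lower levels. The 12 adipocyte genes took 0.876 ± 0.225% of gene reads, led by Car3 at 2817 ± 1068 CPM, the adipsin gene Cfd at 2165 ± 88.0 CPM and Ucp1, the uncoupling protein gene of brown fat, at 1144 ± 768 CPM. Capsule and fibroblast genes took 0.484 ± 0.00860%, with Gsn holding most of these reads and Sparc at 972 ± 48.1 CPM. Antigen presentation genes, led by H2-D1 at 840 ± 43.2 CPM, took 0.204 ± 0.0177%. Haemoglobin and other erythroid genes took 0.176 ± 0.0207%; how these reads divide between the near-identical copies Hba-a1 and Hba-a2, with 1671 and 950 reads together, is uncertain. Endothelial genes, led by Plvap at 227 ± 14.9 CPM, took 0.0619 ± 0.00291%, macrophage genes, led by Lyz2 at 208 ± 5.28 CPM, took 0.0529 ± 0.00773%, and Schwann and glial genes took 0.0297 ± 0.0112%. The liver list took 0.0561 ± 0.0133%, nearly all of it from Trf (915 and 431 reads), while Alb had 4 and 2 reads. The kidney list had 11 reads in replicate 1 and 5 in replicate 2, and the gonadal list 60 and 32 reads. The lymphocyte and plasma cell list had 55 and 21 reads, most of them from Ighm. Of 15 genes tied to senescence and ageing, 11 were detected, led by Igfbp3 at 94.0 ± 1.82 CPM; Cdkn2a had 1 read in replicate 1 and 0 in replicate 2. Imprinted genes took 0.507 ± 0.110%, led by the cell cycle inhibitor gene Cdkn1c at 2221 ± 1035 CPM and by Gnas at 1799 ± 247 CPM. The mitochondrial genome list took 0.0480 ± 0.00441%, led by mt-Co1 at 183 ± 37.1 CPM. As the read filters are not stated, this share is that of the deposited reads and may not be that of the gland.

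**Figure D1:**
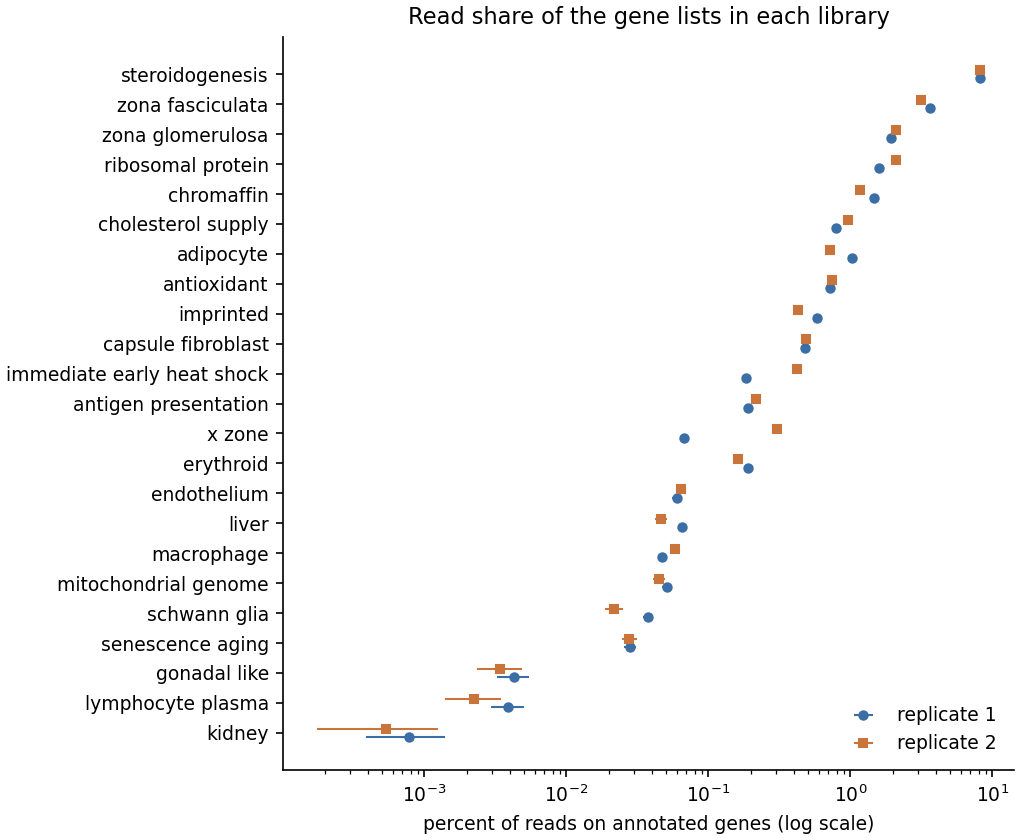
Percent of reads on annotated genes (log axis) held by each of the 23 gene lists in replicate 1 (circles) and replicate 2 (squares), with exact 95% binomial intervals. The steroidogenesis list leads at 8.22% and 8.14%, and the kidney list is lowest at 11 and 5 reads.

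The libraries differed most in a few genes. Akr1c18 was 8.65-fold higher in replicate 2 (interval 7.81 to 9.59), and the stress-inducible chaperone genes Hspa1b and Hspa1a were 4.78-fold (interval 4.32 to 5.30) and 4.35-fold higher (interval 3.70 to 5.13). These 2 chaperone genes are near-identical copies, and their summed reads, 693 and 2180, were 4.65-fold higher in replicate 2 (interval 4.27 to 5.08). Apoc1, an apolipoprotein gene, was 4.74-fold higher in replicate 2 (interval 3.74 to 6.06) and Srd5a2, a steroid reductase gene, 3.11-fold higher (interval 2.48 to 3.92). In the other direction, several genes of skeletal muscle were read almost only in replicate 1. Acta1, the skeletal muscle actin gene, had 333 and 0 reads. With the 0 set at 3 reads it was 75-fold higher in replicate 1 (lower end of the exact interval 60.7). The creatine kinase gene Ckm had 240 and 0 reads, 54.1-fold higher on the same basis (lower end 43.6). The calcium pump gene Atp2a1 had 407 reads and 1 read, a ratio of 275 (interval 49.1 to 10893), with 0 of these reads on annotated transcripts.

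The rest of the 12 genes most in favour of replicate 1 were 2 annotated loci without coding sequence and 7 coding genes. Slc27a2, Ehhadh, Fabp3 and Elovl3, all of fatty acid handling, were 4.18-fold (interval 2.87 to 6.28), 3.66-fold (interval 2.36 to 5.92), 3.54-fold (interval 2.79 to 4.54) and 3.33-fold higher (interval 2.83 to 3.94). Gmpr was 3.87-fold higher (interval 3.19 to 4.73), and Rhcg and Phlda3 were 3.41-fold and 3.02-fold higher. The processed pseudogene Gm15459, which matches Hspa8 over 1924 aligned bases with 98.6% identity, had 5305 and 267 reads. The long non-coding gene AC154200.1 had 116 and 0 reads, whereas its neighbour on the same strand, the pseudogene Oaz1-ps, had 16 and 107. With all overlapping models of the locus pooled, whether or not the annotation gives them to the gene, the log2 ratios at Gm15459 and AC154200.1 were 0.14 and 0.26, so these gene counts depend on how reads were assigned. Hspa8 and Gm15459 summed to 10574 and 4385 reads, without 3686 reads in replicate 2 on a model that abuts Gm15459. Higher in replicate 2 by 3.24-fold to 3.76-fold were Cbarp, Neat1, Abtb2, Myh9, Gm37376 and Crem, the last being a cyclic AMP response regulator gene at 3.24-fold (interval 2.32 to 4.59). Gm37376 lies within the span of Malat1 on the other strand, and Malat1 was itself 2.53-fold higher in replicate 2. Whether reads of Gm37376 come from Malat1 was not tested.

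Across all genes, 16227 were detected in replicate 1, 15565 in replicate 2 and 14085 in both. Across genes, which are not independent replicates, log2 CPM values had a Pearson correlation of 0.943 and a Spearman correlation of 0.929. Of 4377 genes with at least 100 reads, 96.7% lay within 2-fold. An exact two-sided binomial test with Benjamini-Hochberg adjustment, which compares the 2 libraries and not conditions, put 1286 of 11068 genes past an adjusted p of 0.05, with 635 higher in replicate 2 and 651 higher in replicate 1. The spread between the libraries beyond counting error, estimated by edgeR over all genes as a common coefficient of variation, was 21.5%. Set against that spread, 27 genes stood out in edgeR's exact test, 12 higher in replicate 2 and 15 in replicate 1, among them Acta1, Akr1c18, Pik3c2g and Hspa1b. As the spread comes from the same pair of libraries, this marks genes that differ more than most others and does not measure how far further libraries would vary. With overlapping models on the same strand pooled, 8 of the 27 lay within 2-fold. Of the 25 most abundant genes, 21 passed the binomial test and 0 passed edgeR's exact test. With the libraries scaled to spike-in reads, all log2 ratios shifted by -0.33, and the binomial test put 242 genes higher in replicate 2 and 2118 higher in replicate 1.

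**Figure D2:**
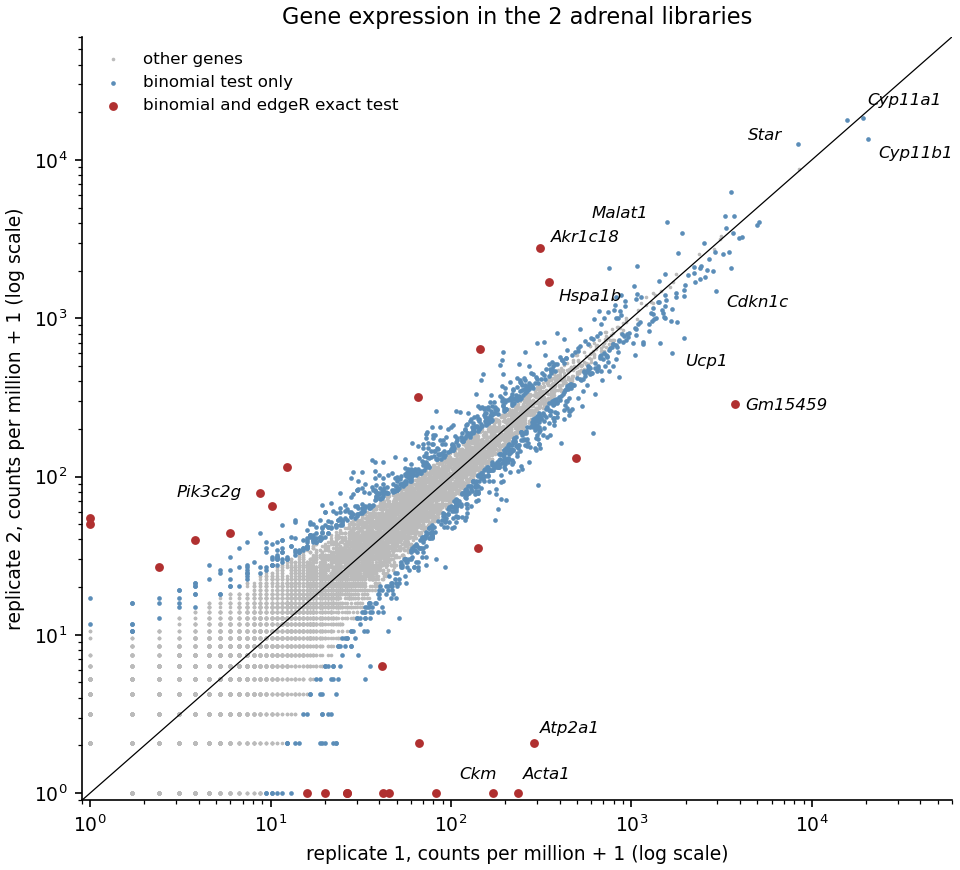
Each point is an annotated gene, with its CPM plus 1 in replicate 1 against replicate 2 (both axes log). Blue points passed the binomial test only, red points are the 27 genes that also passed edgeR's exact test, grey points are other genes, and the line marks equal values; Acta1, Ckm and Atp2a1 lie at the bottom right and Akr1c18, at 441 and 2578 reads, above the line.

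By gene list, steroid synthesis had similar sums over all transcript models, but its genes differed. Of 19 measured steroidogenesis genes, 5 were higher in replicate 2, 6 higher in replicate 1 and 8 did not pass the binomial test (5 and 7 when adjusted over the list alone). Under spike-in scaling the counts were 4 and 12. Fdx1 was 2.69-fold higher in replicate 2 (interval 2.49 to 2.90), Mrap, the partner of the ACTH receptor, 2.13-fold (interval 1.89 to 2.40) and Star 1.47-fold (interval 1.43 to 1.51). Cyp11b1 was 1.54-fold higher in replicate 1 (interval 1.51 to 1.57), and Cyp11b2 was 1.51-fold higher there (interval 1.40 to 1.62). The annotated spans of Cyp11b1 and Cyp11b2 overlap, so their ratios may not be independent. The list's median log2 ratio of -0.14 lay at percentile 23.3 of 10000 random lists of the same size and expression. Among 28 cholesterol supply genes, 6 were higher in replicate 2, such as Apoe at 1.94-fold (interval 1.82 to 2.08), and 4 higher in replicate 1, such as the sterol sensor gene Insig1 at 1.82-fold (interval 1.65 to 2.02); adjusted over the list alone these counts were 6 and 7, and under spike-in scaling 3 and 11.

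Of 19 lists with at least 3 measured genes, 6 had a median outside the central 95% of random lists. The X-zone list was higher in replicate 2, with a median of 1.96 and a random range of -0.51 to 0.53. Its members went both ways: Pik3c2g was 9.82-fold higher in replicate 2 (interval 5.18 to 20.5; 11 and 73 reads), whereas Cyp2f2 was 1.99-fold higher in replicate 1 (interval 1.67 to 2.38), and Thrb, at 10 and 12 reads, did not pass the test. Immediate early and heat shock genes were higher in replicate 2 (median 0.53, random range -0.34 to 0.28), with 6 of 11 higher there and 1, Nr4a1, higher in replicate 1; adjusted over the list alone the counts were the same, and under spike-in scaling they were 3 and 1. Besides Hspa1b and Hspa1a, Hsph1 was 2.02-fold higher (interval 1.81 to 2.26). Ribosomal protein genes were higher in replicate 2 with a median of 0.39 (random range -0.12 to 0.07). Of 79 measured, 34 were higher in replicate 2 and 0 higher in replicate 1 (42 and 0 when adjusted over the list alone). Under spike-in scaling the ribosomal median was 0.06 with 6 genes higher in replicate 2 and 5 in replicate 1, still above the random range of -0.45 to -0.26 that the same scaling gives.

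Adipocyte genes were higher in replicate 1, with a median of -0.46 against a random range of -0.31 to 0.22. Of 12 genes, 7 were higher there and 0 in replicate 2, both over all genes and adjusted over the list alone. Ucp1 was 2.87-fold higher (interval 2.61 to 3.15) and Plin1, a lipid droplet coat gene, 1.89-fold (interval 1.62 to 2.20), while Cfd was 1.08-fold higher (interval 1.02 to 1.15) and Cidea and Fabp4 did not pass the test. Chromaffin genes had a median of -0.27 (random range -0.24 to 0.24), with 6 of 24 higher in replicate 1, among them Th at 1.53-fold (interval 1.41 to 1.65), Chga at 1.31-fold and Chgb at 1.28-fold, and 0 higher in replicate 2 (7 and 0 when adjusted over the list alone). Schwann and glial genes had a median of -0.66 (random range -0.61 to 0.76), resting on 4 genes of which Cnp alone passed the test, at 1.81-fold higher in replicate 1 (interval 1.51 to 2.17). With a minimum of 50 reads per gene, the chromaffin list lay inside the random range, the macrophage list lay above it, and the Schwann list kept only Cnp, too few to be tested.

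Transcript length went with the ratio between the libraries. Among genes with at least 50 reads, those with a main transcript of up to 400 nt had a median log2 ratio of 0.47, those of 2000 to 3000 nt -0.16 and those over 5000 nt 0.22 (43, 1645 and 578 genes). The ribosomal list, which includes Rpl41 with a log2 ratio of 0.41, had a median transcript length of 792 nt. With random lists matched on transcript length as well as expression, the X-zone, heat shock, ribosomal, adipocyte and Schwann lists stayed outside, chromaffin genes lay inside and erythroid genes, led by Hba-a1, lay outside, higher in replicate 1.

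**Figure D3:**
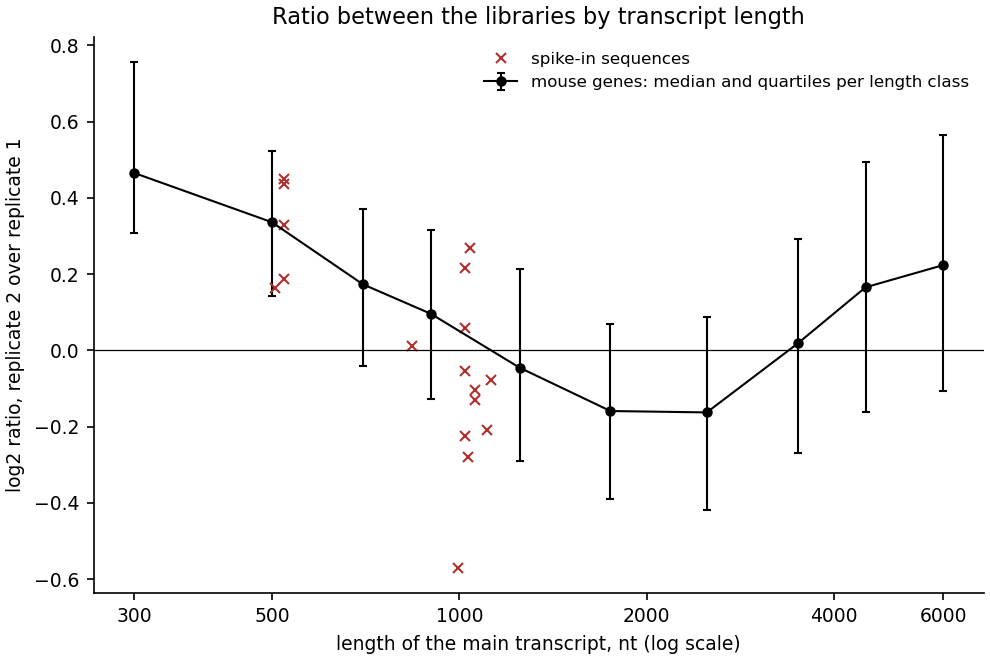
Log2 ratio of replicate 2 over replicate 1 against the length of the main transcript for genes with at least 50 reads, with medians and quartiles of 10 length ranges and spike-in sequences as crosses. Gene ratios are TMM-scaled, whereas spike-in ratios are relative to each library's spike-in total. On that second scale gene log2 ratios would shift by -0.33, so the heights of crosses and genes are not directly comparable. Medians run from 0.47 up to 400 nt through -0.16 at 2000 to 3000 nt to 0.22 over 5000 nt.

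Inside the random range were the remaining 13 lists, some with members past the test. Wnt4, a signalling gene of the zona glomerulosa list, was 1.95-fold higher in replicate 1 (interval 1.69 to 2.25), and Abcb1b of the zona fasciculata list was 1.79-fold higher in replicate 2 (interval 1.70 to 1.89). In antigen presentation, the class II genes Cd74, H2-Ab1, H2-Eb1 and H2-Aa were higher in replicate 2, H2-Aa by 3.16-fold (interval 1.87 to 5.51) and Cd74 by 2.34-fold (interval 1.95 to 2.82), whereas the class I gene H2-K1 was 1.21-fold higher in replicate 1 (interval 1.06 to 1.38); the list alone gave the same 4 and 1. The complement genes C1qa and C1qc of the macrophage list were 1.95-fold and 1.88-fold higher in replicate 2. Of the imprinted genes, Meg3 was 2.73-fold higher in replicate 2 (interval 2.30 to 3.25) and Cdkn1c 2.03-fold higher in replicate 1 (interval 1.91 to 2.16). The gonadal list had too few measured genes to be set against random lists. Its member Foxl2, an ovarian transcription factor gene, had 25 reads in replicate 1 and 1 read in replicate 2, a ratio of 16.9 (interval 2.77 to 694). None of the 13 capsule and fibroblast genes and none of the 8 measured senescence genes passed the binomial test, but under spike-in scaling 7 and 2 of them were higher in replicate 1. The same scaling left 3 antigen presentation genes higher in replicate 2 with 4 in replicate 1, and no macrophage gene past the test.

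**Figure D4:**
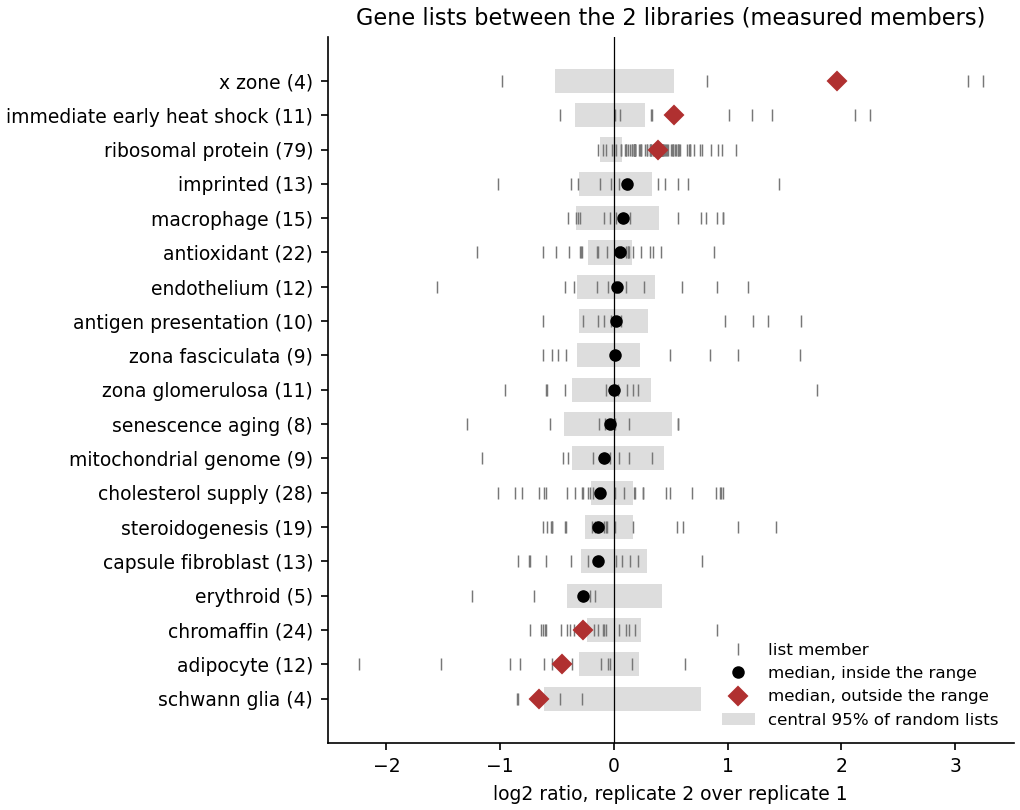
Log2 ratios of replicate 2 over replicate 1 for 19 gene lists, with the number of measured genes in brackets. Ticks are genes, circles and diamonds are list medians, and grey bars are the central 95% of medians of 10000 random lists matched on expression; the 6 diamonds lie outside, from the X-zone list at 1.96 to the Schwann and glial list at -0.66.

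Known isoforms carried most reads. Of all mouse reads, 74.7% in replicate 1 and 69.0% in replicate 2 (mean 71.8 ± 4.06%) were assigned to annotated transcripts. Incomplete splice matches, which hold part of an annotated intron chain, took 11.8% and 12.3%. New combinations of annotated splice sites (NIC) took 4.06 ± 0.297% and isoforms with at least 1 splice site outside the annotation (NNC) took 3.13 ± 0.0880%. Reads classed as genomic took 3.49% and 5.67%, reads classed as antisense 2.72% and 5.05%, and intergenic reads 0.403% and 0.575%. For every class the difference between replicates exceeded the counting intervals.

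Main isoforms were named for 26 of the 32 genes chosen beforehand. Cyp11b1-201 held 87.7 ± 2.23% of Cyp11b1 reads (mean ± SD, n = 2), Star-201 81.6 ± 4.59% of Star reads and Cyp21a1-201 77.8 ± 3.86% of Cyp21a1 reads. For Cyp11a1, the 9-exon Cyp11a1-201 (chromosome 9, 58014671 to 58027023, plus strand, mm10) held 67.1% in replicate 1 and 50.4% in replicate 2, and unannotated single-exon models, the most abundant of them at the 3′ end of the gene, held 24.6% and 38.7%. Hsd3b1 was led by a 4-exon incomplete splice match with 70.3% and 75.8% of its reads, while the annotated Hsd3b1-201 held 11.2% and 0.820%. Counting known transcripts alone therefore gave Hsd3b1 771 CPM. Nr5a1 was likewise led by a 4-exon incomplete splice match, at 42.4 ± 4.35%, with Nr5a1-201 at 28.2%. In the medulla, Chgb-201 held 91.0 ± 0.884%, Chga-201 83.0 ± 2.56% and Th-201 79.7 ± 7.96% of their genes' reads.

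Several genes used more than 1 annotated isoform in like shares in both libraries. Gnas-208 held 51.8% and 50.2% of the reads of Gnas, the gene of a stimulatory G protein subunit, Gnas-207 22.6% and 21.8%, and Gnas-206 11.6% and 11.6%. Pkm-201 held 64.6% and 65.2% of the reads of the pyruvate kinase gene Pkm, and Pkm-202 22.3% and 20.3%. Cd74-201 and Cd74-202 held 52.1 ± 2.28% and 38.1% of Cd74 reads. In Tpm1, a tropomyosin gene, the main annotated isoform held 26.3% and 31.1%, whereas Tpm1-205 had 63 reads in replicate 1 and 0 in replicate 2. Across 6413 genes with at least 20 reads in each library, the median share of the main isoform was 74.6% in replicate 1 and 70.7% in replicate 2, and the main isoform was annotated in 86.9% of genes. In 1270 genes (19.8%) the main isoform held less than 50% of reads in both libraries, a count that fell to 387 with incomplete splice matches and genomic models left out.

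**Figure D5:**
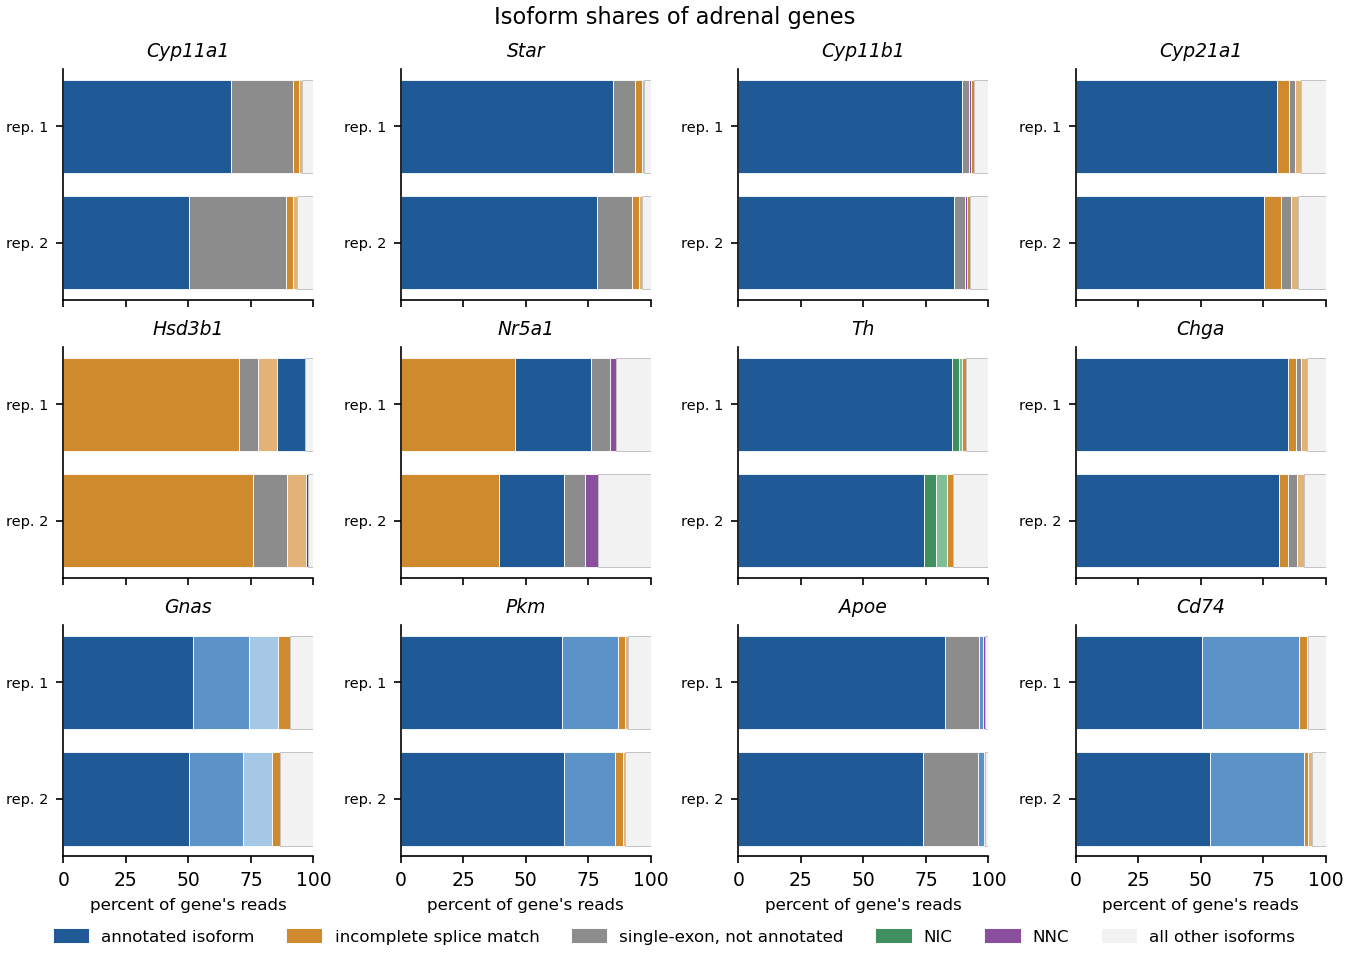
Percent of a gene's reads on its most abundant isoforms in replicates 1 and 2 for 12 genes, coloured by class, with up to 4 isoforms or classes shown and all others in pale grey. Shades of a colour mark different isoforms of a class; single-exon models are larger in replicate 2 for Cyp11a1 (24.6% and 38.7%) and Star (8.86% and 14.0%).

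Isoform shares differed between the libraries in 149 of 6223 tested genes (two-sided Fisher's exact test of the main isoform against the rest, Benjamini-Hochberg adjusted p under 0.05), which compares libraries and not conditions. With single-exon models told apart by exact coordinates, 340 passed. The main isoform had the lower share in replicate 2 in 136 of the 149 and the higher share in 13; across all mouse reads, single-exon models took 11.9% and 16.4%, and annotated transcripts 74.7% and 69.0%. Of the 26 measured panel genes, 13 passed: Cyp11a1, Star, Cyp21a1, Cyp11b1, Akr1b7, Th, Apoe, Fdxr, Chga, Scarb1, Fdx1 and Nr5a1 with a lower share in replicate 2 and Hsd3b1 with a higher share. Th-201 fell from 85.4% in replicate 1 (interval 83.8 to 86.8%) to 74.1% in replicate 2 (interval 71.2 to 76.9%). The largest differences were in genes with few reads. Rnaseh1-201, of an RNA-DNA hybrid nuclease gene, held 95.2% and 51.5% of reads, Rasa4-201 52.3% and 11.1%, Ttc38-203 77.4% and 36.4%, Bhlhb9-204 83.3% and 42.7%, Vps72-201 76.9% and 37.1%, Mri1-203 78.0% and 41.3%, Rgs2-202 89.8% and 54.5%, and Amd1-201 87.2% and 54.1%. Rab4b-201 (35.2% and 72.7%) and Vps39-201 (40.4% and 75.6%) had the higher share in replicate 2. With incomplete splice matches and genomic models left out, 53 genes passed, 36 of the 149 among them, and of the 8 named genes still measured Rasa4 and Vps39 passed. The other 6 did not pass. Main isoform shares were then 87.3% and 58.2% for Bhlhb9, 88.5% and 54.3% for Mri1, 100% and 60.7% for Rnaseh1, 98.1% and 78.3% for Rgs2, 97.6% and 80.0% for Amd1, and 81.0% and 91.4% for Rab4b (Benjamini-Hochberg adjusted p from Fisher's exact test 0.0536, 0.0596, 0.0817, 0.277, 0.450 and 0.880). In Rab4b an incomplete splice match with 80 and 0 reads made most of the difference. It lies at 27158658 to 27164983 on chromosome 7, apart from Rab4b-201 at 27168424 to 27178896. In Bhlhb9 (chromosome X) an NNC model with 0 and 11 reads, at 135839034 to 135842949, likewise lies apart from Bhlhb9-204, at 135885851 to 135891078. So does the leading model of its unannotated single-exon class (0 and 17 reads), at 135798473 to 135803466. For both genes the shares depend on which reads were assigned to the gene.

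Most new spliced isoforms with several reads were read in both libraries. Of 3158 NIC or NNC isoforms with at least 5 reads in a library, 2917 (92.4%) were also read in the other library, matched by identical intron chains. The share depends on the read minimum: at 1 read it was 16.5% of 70289. By class the shares were 94.0% of 2161 NIC and 90.1% of 1117 NNC isoforms, where chains classed differently in each library count under both. The most abundant was an NIC form of Oaz1, the antizyme gene of polyamine control (chromosome 10, 80826656 to 80829284, plus strand), with 1795 and 1238 reads, or 94.4% of the gene's reads in both libraries. It differs from Oaz1-201 only by keeping a gap of 4 nt that the annotation treats as an intron, at 80828292 to 80828295. The same holds for Oaz2, where the NIC form held 91.2% and 83.1% of reads and kept a 4 nt gap at 65686269 to 65686272 on chromosome 9. Mpc1, a mitochondrial pyruvate carrier gene, was read mainly as an NIC form (93.2% and 92.8%) with an intron of 12573 nt, at 8283962 to 8296534 on chromosome 17, that is not annotated. NNC forms led Cct6a (89.2 ± 1.04%), Chmp1a (83.8 ± 0.255%), Idh3g (68.8 ± 2.32%) and Hnrnpk (33.9 ± 2.35%). In Idh3g the new intron spans 73782104 to 73782670 on chromosome X, minus strand, in place of 2 annotated introns. These lie at 73782104 to 73782297 and 73782310 to 73782674, around a very short exon. In Hnrnpk the new intron lies at 58393775 to 58394059 on chromosome 13. It replaces introns at 58393775 to 58393852 and 58393869 to 58394075, again around a very short exon. The new introns stop at 73782670 in Idh3g and 58394059 in Hnrnpk, short of the annotated intron ends at 73782674 and 58394075. Skipping of the short exon between annotated splice sites would give introns that reach those ends. The coordinates therefore argue against such skipping in both genes. Whether the bases of the short exon were aligned to a neighbouring exon was not tested. Cdkn1c had 3 NIC forms with 26.1 ± 1.47%, then 13.2% and 10.9%, and 11.0% and 9.78% of its reads. The counting intervals of the libraries overlapped for each of these isoforms except that of Oaz2, where they were 88.5 to 93.5% and 77.7 to 87.7%.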

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

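The tests on Pik3c2g and the other Akr1c genes, on Cyp2f2, on muscle and fat genes and on ribosomal protein genes and spike-ins were chosen after the results were seen. The length prediction for Akr1c18 was written before that test was run, but for a pattern already seen in the gene ratios. The series has 1 group, so the design gives no biological explanation to test; explanations by cell content were tested on marker genes alone.

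A signal in data outside the gene tests is the share of reads that the deposited tables class as antisense, which was 2.72% of mouse reads in replicate 1 (interval 2.69 to 2.74%) and 5.05% in replicate 2 (50061 of 991989 reads, of which 3686 lie on a model with no gene on the other strand). Spike-ins, which have no antisense transcripts, gave 1.17% (interval 1.02 to 1.34%) and 0.990% (interval 0.841 to 1.16%).

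Akr1c18 and Pik3c2g, both listed for the X-zone, were 8.65-fold and 9.82-fold higher in replicate 2. Reads moved from neighbouring Akr1c genes do not account for Akr1c18, since those genes lost only 6.96% of what it gained. Length bias is argued against too: genes of like length had median log2 ratios of 0.00120 for Akr1c18 (340 genes) and -0.17 for Pik3c2g (744 genes). More cells that carry all 4 listed genes are argued against by Cyp2f2, at -0.99 (interval -1.25 to -0.74). A difference in which part of the cortex was sampled, or between animals if the libraries come from separate animals, was not tested, stays open and may involve cells with Akr1c18 and Pik3c2g but without Cyp2f2.

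Skeletal muscle genes and, by their median, thermogenic fat genes were higher in replicate 1. Of the 14 thermogenic genes, 5 had higher values in replicate 2. RNA from skeletal muscle in that library could account for the muscle part, but the muscle list gives no independent test of it. The 14 other measured muscle genes, beside Acta1, Ckm and Atp2a1, had a median log2 ratio of -3.73 (random range -0.44 to 0.45). All 14 were lower in replicate 2, and with zeros at their bound the median was -2.39. The list was chosen after gene ratios had been seen, and Tnnc2 and Myh1 of the 14 already stood out in edgeR's exact test. Of all 17 measured members, 7 had 0 reads in a library and passed the read minimum through the other alone. Whether the fat part is more fat of the same make-up cannot be told apart from a change in its make-up, since thermogenic minus general adipocyte genes gave -0.20 (bootstrap interval -1.18 to 0.70). Whether muscle and fat came as 1 change of the same size is left open. The difference of their medians was -1.64 (bootstrap interval -3.29 to -0.01), and the interval reaches inside the gap of 1 allowed for a like size. The bootstrap resamples genes of lists chosen after ratios had been seen, so it cannot decide whether the medians are equal.

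Ribosomal protein genes were higher in replicate 2. Transcript length as the whole cause is argued against only as far as the matching in 10 length bins reaches. The list median of 0.39 lay above the range of random lists matched on length, 0.07 to 0.24, and exceeded their median by 0.23. Among short transcripts the median ratio itself fell from 0.47 up to 400 nt to 0.10 at 800 to 1000 nt. A length effect within a bin is therefore not excluded. Length bias made in the library steps could account for part: spike-ins of 505 to 523 nt had a median log2 ratio 0.42 above those of 840 to 1124 nt (5 and 12 sequences, exact permutation p = 0.00339 over 6188 splits). What accounts for the rest, a length effect within a bin included, stays open.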

How the results depend on the processing

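The pooling of loci, the exact coordinates of single-exon models, the random lists matched on length and the spike-in scaling of list counts and of the coefficient of variation were chosen after the results were seen. Of 119 alternatives, 87 left the result on its side, 9 weakened it, 3 strengthened it, 16 moved it and 4 reversed it. Most were single genes: 25 abundant genes and 22 ratio genes on known transcripts only, and 27 called genes with loci pooled. These gave 12, 22 and 19 of the 87. A count was taken as left on its side when it changed by at most 1.5-fold. Known transcripts took 83.9% of reads with incomplete splice matches counted as known and 80.2% over models of 5 or more reads, where single-read models drop out. Genes differing between libraries numbered 2360 with spike-in totals and 27 in edgeR's exact test, which allows for the spread between these libraries. The steroidogenesis share was 7.44 ± 0.478% on known transcripts, where most Hsd3b1 reads drop out. Genes with a main isoform under 50% numbered 387 without incomplete splice matches and genomic models and 547 at 50 reads, where fewer genes qualify. Genes with different isoform composition numbered 53 without those models and 340 with single-exon models told apart by coordinates. New isoforms in both libraries numbered 11619 at 1 read (16.5% of 70289), 1181 at 10 reads (98.5% of 1199) and 2328 with both ends within 100 bp (73.7%). With loci pooled, log2 ratios turned to 0.14 for Gm15459, 0.26 for AC154200.1, -0.61 for Podn and -0.31 for Rtl8c, where reads of a neighbouring model joined the count. Where no reason is given, the cause was not tested.

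Other values kept their side: 10222 to 13659 genes in both libraries, a coefficient of variation of 20.5 to 21.7% (26.9% with spike-in totals), 961 to 1293 differing genes under other scalings and filters, and 155 to 176 genes differing in isoforms. All 22 named ratios measurable on known transcripts kept their direction, and Atp2a1 and AC154200.1 had no reads there; 13 of the 25 most abundant genes moved in level. No paired analysis was possible because the series has 1 group. Matching of new models by identifier was not run, since no new identifier is shared. Depth limits isoform measures to 6413 genes, of which 6223 have more than 1 isoform to test.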

Other observations

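The lists in these paragraphs were chosen after gene ratios had been seen. Skeletal muscle genes had 1522 reads in replicate 1 and 104 in replicate 2, with a median log2 ratio of -3.83 over 17 measured genes (-3.02 with zeros at their bound). Of these, 12 were higher in replicate 1 and 0 in replicate 2 (14 and 0 when adjusted over the list alone). The troponin gene Tnnc2 had 63 and 0 reads and the myosin gene Myh1 58 and 0 reads. With the 0 set at 3 reads they were 14.2-fold and 13.1-fold higher in replicate 1 (lower ends of the exact intervals 11.2 and 10.3). Of the 22 listed genes, 3 had more than 3 reads in replicate 2: Eno3 (102 and 55), Tpm2 (65 and 19) and Pygm (49 and 20). Thermogenic fat genes took 0.391% and 0.180% of gene reads, with a median of -0.75 and 8 of 14 past the test as higher in replicate 1 (8 when adjusted over the list alone). By value 9 of the 14 were lower in replicate 2 and 5 higher, of which 0 passed the test. General adipocyte genes took 0.798% and 0.592%, with a median of -0.55; all 13 had lower values in replicate 2 and 11 passed the test, among them the lipase gene Lpl at 2.11-fold. The other Akr1c genes took 0.155% and 0.141%.

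Nuclear-retained noncoding RNAs took 0.193% of gene reads in replicate 1 and 0.477% in replicate 2, with a median log2 ratio of 1.34 over 5 measured genes. Malat1 was 2.53-fold higher in replicate 2 (interval 2.40 to 2.67), Neat1 3.50-fold and Meg3 2.73-fold, and 0 of the 5 passed the test as higher in replicate 1. Also higher in replicate 2 were the shares of genomic reads (3.49% and 5.67%), of antisense reads (2.72% and 5.05%) and of single-exon reads (11.9% and 16.4%).

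Reads classed as antisense were on single-exon models for 96.5% of reads in replicate 1 and 97.6% in replicate 2. The most abundant lay opposite Gm26917 (chromosome 17, 39843013 to 39846245, minus strand; 3541 and 4325 reads). Next in replicate 2, with 3686 reads, was a model of 86 nt at 5781530 to 5781615 on chromosome 5, opposite no gene and next to Gm15459 on the same strand. The leading models opposite Actb had 1836 and 1855 reads.

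Of 27 genes called by edgeR's exact test, 19 stayed over 2-fold with loci pooled and 8 did not. Besides the 4 that turned, Gm15432, Gm14592, Oaz1-ps and Gm45233 had pooled log2 ratios of -0.50, -0.33, 0.26 and 0.13. The pooled loci of Podn and Gm45233 were mostly reads of Scp2 and Etfb.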
